A study of Caenorhabditis elegans with 4 samples.

How the data were processed

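The samples were 4 genomic DNA libraries of Caenorhabditis elegans, 2 from anti-GFP chromatin immunoprecipitation (ChIP) and 2 from input chromatin, numbered 1 and 2 in each group by their titles. Per the labels' protocols, starved and synchronised larvae were fed E. coli HB101 at 20 °C, crosslinked with formaldehyde, lysed and sonicated. A part of each lysate was kept as input, and the rest was incubated with anti-GFP antibody on protein G beads. The labels do not say whether replicates 1 and 2 came from separate cultures, so differences between them measure only the spread between these libraries, which may be technical.

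The deposited files used here were 3 peak lists, 1 for each ChIP replicate and 1 combined list, and all carried WormBase WS220 as genome build, per the file headers. The replicate lists name SPP run through the IDR procedure as their source, per the file headers and source columns, and give each peak a score whose scale is not stated. The highest score was shared by 1238 peaks in replicate 1 and by 512 peaks in replicate 2. The combined list names PeakSeq as its source, and the authors deposited a q-value for each of its peaks, with a maximum of 0.00999. The combined list therefore came from a different caller than the replicate lists. How the replicates were pooled for it, the aligner, the software versions and the read depths are not given in the sources used here. The lists hold no read counts, so the depth behind a peak is unknown, and no interval below covers sequencing error. Intervals printed with shares of peaks are exact 95% binomial (Clopper-Pearson) intervals that cover the counting of peaks only. They treat peaks as independent, although neighbouring peaks are not always so.

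Peaks of a replicate list were ranked by the authors' score, and ties were broken by the peak number that the authors put in each peak's name. Because of the ties, the order of the first 1238 ranks of replicate 1 and of the first 512 ranks of replicate 2 is the order of these numbers alone, so the strongest 100, 200 and 474 of both lists were chosen by number. What the numbers rank by is not stated. After the data were seen, the numbers were checked among the tied peaks outside chromosome I, against the combined q-values. These came from another caller but from the same ChIP libraries, so the check is not independent of the reads. Over combined regions whose best peak was tied, a lower number went with a lower combined q-value, with a Spearman's rho across regions of 0.58 in replicate 1 (389 regions) and 0.53 in replicate 2 (238 regions), each with a one-sided permutation p of 0.0001, the smallest that 10000 resamples can give. Combined peaks were ranked by q-value. Peaks on mitochondrial DNA were kept apart, and all tests between lists used the 6 nuclear chromosomes. Lists of the strongest peaks leave mitochondrial peaks out, while the rank printed for the best peak under a combined region counts them. The largest peak end in any list stood for the length of a chromosome, 100236684 bp over the nuclear chromosomes. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. Chance overlap came from 10000 circular shifts, in which all peaks of a list were moved along each chromosome by a random distance. This keeps the number, widths and spacing of the peaks. The distance had no lower limit, so a very short shift can keep true overlaps in place and raise the highest count. The smallest one-sided p-value that these shifts can give is 0.0001. Chromosome shares were compared with the share of chromosome length by two-sided exact binomial tests with Benjamini-Hochberg adjustment over the chromosomes. Peak strength was compared over uniquely paired peaks by Spearman's rho of the scores and Pearson's r of their natural logarithms, with intervals from 1000 bootstrap draws over peaks. The lists of the strongest peaks were compared at equal length, and 474 peaks, the length of the combined list, was the usual length.

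The overlap comparisons and the X chromosome share were set before the data were examined, with their alternatives except 3. These were peak strength without the highest scores and the X share without broad regions or without chromosome I. The shares of the other chromosomes, the recovery of strong peaks per chromosome, the spacing of peaks and the position along chromosomes were added after seeing the data. Before the data were examined, the genes nearest to the 25 strongest combined peaks were to be named, and tests of distance to gene starts, of sequence motifs and of fixed gene and cell type marker lists were planned. These need an annotation or sequence of WS220. The reference table at hand is of the WBcel235 assembly and holds no strand, so its positions were not joined to the peaks and these tests were not run. The 25 strongest combined peaks are named by position instead, and that table was used only for the chromosome of 2 genes. Positions are 1-based WS220 coordinates.

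The circular shift test was tested on simulated data. With 2000 replicate 1 peaks of the 23912 nuclear ones planted in a simulated second list, the overlap above chance, corrected for chance overlap, was 1999 peaks. With none planted, the p-value was 0.836, and among 200 random lists of 2000 peaks 3.0% had a p-value of 0.05 or less. Planted peaks were exact copies and all other simulated peaks were placed uniformly at random, so their recovery only checks the computation. Real libraries can share places of uneven coverage or mappability, which neither the simulated lists nor the circular shifts reproduce. An overlap above the shifts can therefore include such places. Alternatives were a reciprocal overlap of at least 50%, midpoints within 200 bp, the stronger 50% of each list, and lists from a single replicate. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.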

Results

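Binding of AHA-1 was mapped in fed first-stage (L1) larvae by ChIP followed by sequencing. AHA-1 is the C. elegans ortholog of mammalian ARNT, a basic helix-loop-helix PAS protein that binds DNA together with partners such as the hypoxia factor HIF-1 and the aryl hydrocarbon receptor AHR-1. The strain, OP124, was an unc-119(ed3) mutant that carried an integrated aha-1 transgene tagged with TY1, EGFP and FLAG, brought in with an unc-119 rescue marker by particle bombardment and outcrossed 3 times. The series held 2 ChIP and 2 input libraries. The ChIP libraries were represented by 1 peak list each and by 1 combined list, and values of the input libraries were not analysed here. There was a single stage and strain, so the design implies comparisons between replicates, between the replicate lists and the combined list, and between chromosomes.

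The combined list held 474 regions that together covered 0.211 Mb of the nuclear genome, or 0.211%. The median width was 348 bp, with an interquartile range of 304 to 466 bp. At the authors' q-value, 277 regions (58.4%) were at or below 0.001, 123 were at or below 1e-05 and 12 were at or below 1e-20. Replicate 1 had 23943 peaks and replicate 2 had 20827. Their nuclear peaks covered 9.38% and 9.42% of the genome. Nearly all peaks of a replicate had the same width, 410 bp for 23921 peaks of replicate 1 and 484 bp for 20819 peaks of replicate 2. The only exceptions were 22 narrower peaks in replicate 1 and 8 in replicate 2.

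Among the 25 strongest combined regions were sharp sites that ranked at the top of both replicate lists. All ranks in this paragraph lie within the tied highest scores, so their order is that of the authors' peak numbers. The region at chromosome V, 10466494 to 10467044 (551 bp), had a q-value of 5.59e-56 and held the first-ranked peak of both replicates. Of the 16 regions under 1500 bp among these 25, 6 held a peak within the first 20 nuclear and mitochondrial ranks of both replicates. Besides the first, these were V from 4131385 to 4131911 (q = 4.60e-33, ranks 4 and 7 in replicates 1 and 2), IV from 4025831 to 4026316 (q = 6.52e-22, ranks 9 and 10) and IV from 14219612 to 14220036 (q = 6.24e-21, ranks 16 and 12). The other two were III from 3867378 to 3867743 (q = 1.96e-19, ranks 6 and 16) and IV from 654699 to 655103 (q = 1.27e-18, ranks 11 and 8). On chromosome III, the region from 10758893 to 10759408 (q = 4.36e-19) had ranks 21 and 20. On X, the region from 4142059 to 4143060 (q = 3.70e-45) had ranks 23 and 4.

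The 5 lowest q-values belonged to broad regions, whose best rank was 339 in replicate 1 and 18 in replicate 2. These were V from 1432017 to 1435552 (q = 2.09e-142), I from 15063993 to 15067649 (q = 4.90e-139), II from 9169864 to 9172591 (q = 1.73e-103), and III from 10906183 to 10909768 (q = 1.06e-81) and from 10904028 to 10905624 (q = 8.21e-73). Their best replicate 1 ranks were 494, none, 339, 1263 and 1004, and their best replicate 2 ranks were 24, none, 18, 401 and 30. Ranks up to 1238 in replicate 1 and 512 in replicate 2 share the list's highest score. Of the ranks just given, only 1263 lies beyond these ties, so the gap to the sharp sites is mostly one of peak numbers. The chromosome I region, at the right end where the large ribosomal RNA gene repeats lie, held no peak in either replicate list. Regions of 1500 bp or more numbered 10 in all, and 9 of them were among the 25 lowest q-values. Other broad regions in this group were X from 1503629 to 1505244 (ranks 8 and 31), X from 16929351 to 16931890 (ranks 95 and 103), IV from 14032571 to 14034216 (ranks 528 and 90) and X from 6740267 to 6742448 (ranks 292 and 1051).

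The rest of the 25 were narrower. V from 264905 to 266007 had ranks 1802 and 165, and III from 10224464 to 10225356 had ranks 416 and 1294. A pair on chromosome II lay close together, from 11759178 to 11759632 (ranks 358 and 100) and from 11761630 to 11762134 (ranks 1137 and 294). IV from 4749877 to 4750241 had ranks 12 and 134, X from 14525565 to 14526170 had ranks 82 and 42, III from 4281884 to 4282572 had ranks 72 and 136, and V from 6224320 to 6225534 had ranks 48 and 199.

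**Figure D1:**
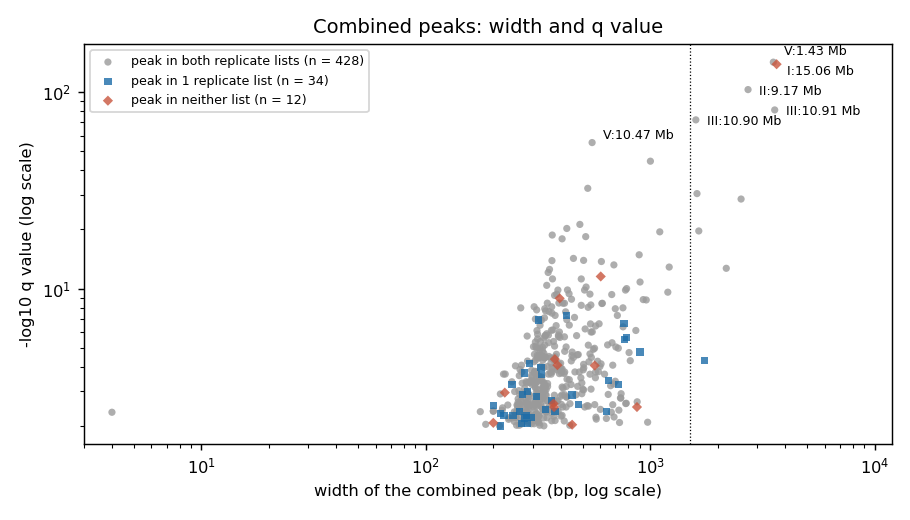
Width in bp (horizontal, log scale) against the authors' q-value as -log10 (vertical, log scale) for the 474 combined regions, with the 6 lowest q-values labelled by chromosome and position in Mb and a dotted line at 1500 bp. Points show regions with a peak in both replicate lists (428), in 1 list (34) or in neither (12), and the 5 lowest q-values all lie to the right of the line.

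The share of peaks found in the other replicate was highest among the strongest peaks. Ranks within the highest score, which covers the first 1238 of replicate 1 and the first 512 of replicate 2, follow the authors' peak numbers. Of the 500 strongest nuclear peaks of replicate 1, 82.4% (95% interval 78.8 to 85.6) overlapped some replicate 2 peak, and of the 500 strongest of replicate 2, 84.0% (80.5 to 87.1) overlapped some replicate 1 peak. The share fell to 36.1% at replicate 1 ranks 1001 to 2000 and to 19.9% (19.1 to 20.7) beyond rank 15000. In replicate 2 it was 24.3% (23.2 to 25.4) beyond rank 15000. Over the whole list, 5887 of 23912 replicate 1 peaks (24.6%) were overlapped, against 16.6% by chance. No circular shift gave more than 18.3%, and the one-sided permutation p was 0.0001, the smallest possible. In the other direction 28.5% of replicate 2 peaks were overlapped, against 19.4% by chance.

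**Figure D2:**
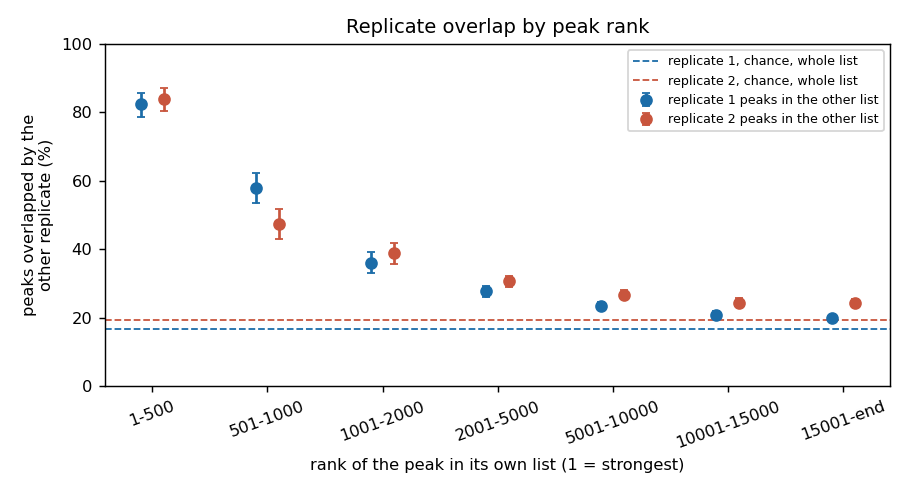
Share of peaks (vertical, %) overlapped by any peak of the other replicate, by rank of the peak in its own list (horizontal, 1 is the strongest), with exact 95% intervals over peaks as error bars. Dashed lines show the chance share of each whole list, 16.6% for replicate 1 and 19.4% for replicate 2. The shares fell from 82.4% and 84.0% at the first 500 ranks to 19.9% and 24.3% in the last band, still above these lines.

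At equal list length, 45 of the 100 strongest peaks of replicate 1 overlapped one of the 100 strongest of replicate 2, where circular shifts gave a mean of 0.091 and a maximum of 12. The maximum can come from very short shifts, which keep true overlaps in place. The numbers were 105 of 200, 227 of 500, 381 of 1000, 568 of 2000 and 1020 of 5000, with chance means of 0.357, 2.25, 8.82, 34.7 and 212. The permutation p was 0.0001 at each of the 6 lengths, the smallest possible, one-sided. The midpoints of uniquely paired peaks that were both among the 474 strongest lay a median of 27 bp apart (interquartile range 14 to 44, 144 pairs). Those of all 3984 pairs, many of which may be chance overlaps, lay a median of 183 bp apart (71.0 to 306).

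The order of peak strength was shared in part, by an amount that depended on which peaks entered. Over the 3984 uniquely paired peaks, Spearman's rho between the scores was 0.27 (95% bootstrap interval 0.24 to 0.31) and Pearson's r of the log scores was 0.30. These are correlations across peaks, which are not independent replicates. Many pairs may be chance overlaps, since circular shifts gave a mean of 3979.6 overlapped replicate 1 peaks against 5887 observed. Such pairs could dilute agreement at shared sites. Over pairs that overlap a combined region, however, rho was no higher, at 0.17 (0.053 to 0.28, 295 pairs). In the stronger 50% of each list rho was 0.43 (0.39 to 0.48, 1668 pairs). Without the pairs in which a peak had its list's highest score, rho was 0.055 (0.021 to 0.088, 3430 pairs).

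The combined list drew on places present in both replicates. Of its 474 regions, 428 (90.3%, 95% interval 87.3 to 92.8) overlapped a peak in both lists, 29 in replicate 1 alone, 5 in replicate 2 alone and 12 in neither. Chance alone would place a replicate 1 peak on 18.4% of the regions and a replicate 2 peak on 17.1%, against 96.4% and 91.4% observed, each with a one-sided permutation p of 0.0001, the smallest possible. The combined list comes from the same ChIP libraries, so overlap above chance was built in and these p-values are no separate support. The best peak under a region had a median rank of 291 in replicate 1 and of 364 in replicate 2. Conversely, 97 of the 100 strongest replicate 1 peaks and 92 of the 100 strongest replicate 2 peaks lay in a combined region. Among the 474 strongest the numbers were 325 (68.6%) and 274 (57.8%), and among the 1000 strongest the shares were 42.5% and 33.7%. Among the 12 regions with no replicate peak, the q-values ran from 4.90e-139 to 0.00935. The strongest of these after the chromosome I end were III from 931226 to 931827 (q = 3.05e-12) and IV from 13549272 to 13549666 (q = 1.22e-09).

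Chromosome I stood apart in the combined list. It held 24 regions, 5.06% of the list (95% interval 3.27 to 7.44), and makes up 15.03% of the nuclear length (exact binomial, adjusted p = 7.22e-11). The replicate lists showed no such shortfall. Chromosome I held 16.9% of the 474 strongest peaks of replicate 1 (13.6 to 20.6) and 16.245% of those of replicate 2 (13.04 to 19.9). Of the 221 replicate 1 peaks that were among the 474 strongest and overlapped one of the 474 strongest of replicate 2, 33 lay on chromosome I. A combined region covered 14 of these 33 (42.4%), against 184 of the 188 elsewhere (97.9%), an odds ratio of 0.0168 (95% interval 0.00364 to 0.0591, two-sided Fisher's exact p = 4.25e-15). Strong peaks of both replicates without a combined region included I from 12652071 to 12652480 (ranks 83 and 212), I from 3824226 to 3824635 (ranks 162 and 45) and I from 12524259 to 12524668 (ranks 221 and 52). On each other chromosome at least 96.2% of such peaks were covered.

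**Figure D3:**
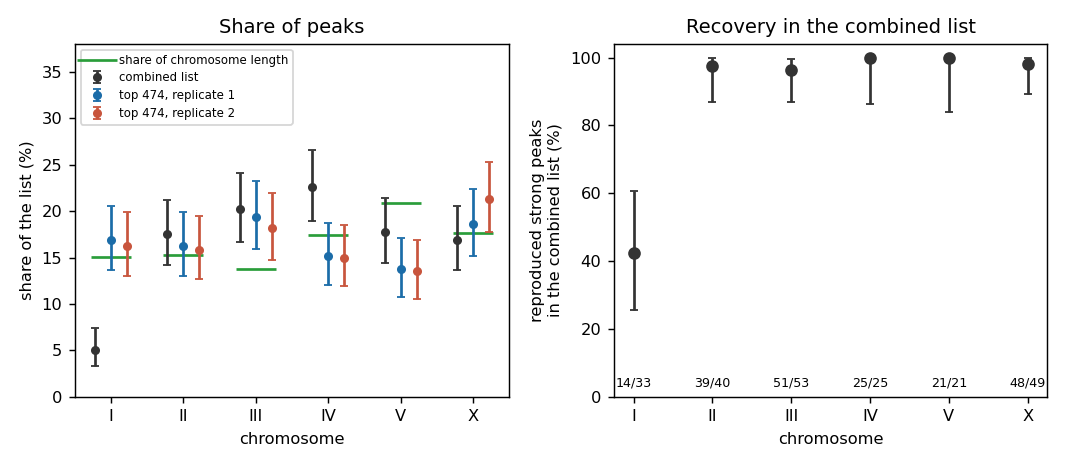
Left, share of peaks per chromosome (vertical, %) in the combined list and in the 474 strongest peaks of each replicate, with exact 95% intervals over peaks as error bars and green lines for the share of chromosome length. Right, share (vertical, %) of strong peaks found in both replicates that a combined region covered, with the numbers at the base, 14 of 33 on chromosome I and 21 to 51 peaks covered on each other chromosome.

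The X chromosome held 80 combined regions, 16.9% of the list (13.6 to 20.6), which did not differ detectably from its 17.7% of the length (exact binomial p = 0.718, adjusted over 6 chromosomes also 0.718). By the same exact test, chromosome III was above its length share, with 96 regions (20.3% against 13.7%, adjusted p = 3.01e-04), and so were the 474 strongest peaks of replicate 1 (19.4%, adjusted p = 0.00191) and of replicate 2 (18.1%, adjusted p = 0.0224). Chromosome V held 17.7% of the combined list against 20.9% of the length (exact, adjusted p = 0.151). Its share was 13.7% of the strongest peaks of replicate 1 (exact, adjusted p = 4.33e-04) and 13.5% of those of replicate 2 (adjusted p = 2.65e-04). Chromosome IV was above its length share in the combined list (22.6% against 17.5%, exact, adjusted p = 0.00876) but not in the strongest peaks of the replicates (15.2% and 14.98%). With chromosome I left out, III remained above (21.3% against 16.17%, exact, adjusted p = 0.00975), V was below (18.7% against 24.6%, adjusted p = 0.00975), and neither IV (23.8% against 20.5%, adjusted p = 0.146) nor X (17.8% against 20.8%, adjusted p = 0.146) passed the test.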

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

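The test in this part was specified before its value was known. Mitochondrial DNA, outside the nuclear comparisons, carried 31 peaks in replicate 1 and 24 in replicate 2, and none in the combined list. The control samples of this design, the input libraries, were not analysed here, so the peaks could not be set against them. They covered 72.3% of the 13511 bp reached by peaks in replicate 1 and 67.6% in replicate 2, a density of 2.29 and 1.78 peaks per kb. Of the 20 strongest peaks of each list, 7 in replicate 1 and 8 in replicate 2 were mitochondrial. Of all mitochondrial peaks, 26 of 31 in replicate 1 and 21 of 24 in replicate 2 had the list's highest score.

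The many copies of mitochondrial DNA in a cell are a candidate cause. On their own, with no preferred sites, they were taken to place the peaks of the 2 replicates independently. The nearest replicate 2 midpoint lay a median of 98.0 bp from a replicate 1 midpoint, against a median of 146 bp over all 13511 circular shifts (one-sided permutation p = 0.0237). If that assumption holds, this argues against copy number without preferred sites as the whole cause. Dense peaks of fixed width on a reference with the same ends could also align the lists, which was not tested. Copy number together with places of uneven coverage or mappability shared by the libraries stays open, and input reads, which could settle it, were not analysed here. No biological explanation was tested.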

How the results depend on the processing

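Each overlap between the replicates stayed above chance under each alternative run for it, with a permutation p of 0.0001 throughout. The share of replicate 1 peaks overlapped was 14.7% with a reciprocal overlap of at least 50% (8.11% by chance) and 14.5% with midpoints within 200 bp (7.94% by chance). It was 18.9% in the stronger 50% of each list (8.61% by chance). The agreement of peak strength moved from a rho of 0.27 to 0.17 for pairs that overlap a combined region, 0.43 in the stronger 50% of each list and 0.055 without the highest scores (an alternative chosen after seeing the data). Fewer combined regions had a peak in both lists when only the 1000 strongest of each were used, 276 in place of 428, because fewer peaks entered. With a reciprocal overlap of at least 50%, 360 regions (75.9%) had a peak in both lists and 43 in neither. The X share, which was below the length share without passing the test, lay above it at 19.4% in the stronger 50% of the combined list (exact p = 0.495). It was 18.6% to 21.3% when the strongest peaks of a single replicate replaced the combined list, and neither replicate passed the test after adjustment (exact binomial, replicate 2 p = 0.0406 unadjusted and 0.0812 adjusted). The cause was not tested. The X share was 16.6% without regions of 1500 bp or more (exact p = 0.584) and 17.8% without chromosome I, against 20.8% of the remaining length (exact p = 0.117). With a single replicate's strongest peaks, the chromosome I share turned from below to above its length share, 16.245% to 16.9%. It was 3.797% in the stronger 50% of the combined list and 4.96% without regions of 1500 bp or more. The odds ratio of recovery on chromosome I was 0.0823 for the 1000 strongest peaks, 0.0172 from replicate 2 peaks and 0.0428 with midpoints within 200 bp. Gene start, motif and gene list tests were not run. No paired analysis was possible because only peak lists of the ChIP libraries were analysed here, without values of the input libraries to pair them with. Depth is unknown, so a peak absent from a list cannot be told from one missed for want of reads.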

Other observations

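The spacing and position tests, the comparison with neighbouring ranks, the check of the peak numbers and the kept and lost ranks in replicate 2 were chosen after the data were seen. Combined regions lay in groups along the chromosomes. Of the 474 regions, 87 (18.4%) had another within 5 kb, midpoint to midpoint. Uniform placement with the same number per chromosome gave a mean of 24.2 and a maximum of 50 over 10000 draws, and drawing places from the replicate peaks gave a mean of 26.4 and a maximum of 58 (one-sided permutation p = 0.0001 for each, the smallest possible). Without the regions of 1500 bp or more, 84 of 464 had a neighbour. The 87 regions formed 37 groups, 28 of them pairs. Whether some groups are a single enriched segment that the caller split was not tested. The largest group held 5 regions on chromosome II from 10548662 to 10563673, with a best q-value of 1.64e-08. Groups of 4 lay on III from 1921050 to 1926783 (best q = 4.08e-09) and on X from 6737316 to 6744220 (best q = 2.13e-13).

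The middle of the chromosomes, the central 1 of 3 equal parts of each, held 35.2% of the combined regions (95% interval 30.9 to 39.7, two-sided exact binomial against an even spread, p = 0.381, adjusted p = 0.52 over 15 such tests). It held 34.8% of all replicate 1 peaks (exact, adjusted p = 6.75e-06) and 35.4% of all replicate 2 peaks (adjusted p = 1.64e-09). On the autosomes alone these shares were 35.4% and 35.9%, and on X they were 31.99% (exact, adjusted p = 0.184) and 33.1% (adjusted p = 0.833), and the difference between X and autosomes was not tested.

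The low share of chromosome I in the combined list could reflect few enriched sites on this chromosome. Its share of the 474 strongest peaks, at least 16.245% in each replicate, argues against that and places the loss in the combined list. The odds ratio of 0.0168 for recovery describes the same gap peak by peak. It largely follows from these shares, so it is no separate support. Loss of rows regardless of strength is argued against because the 19 strong peaks without a combined region ranked behind the 14 with one (median replicate 1 rank 223 against 114, one-sided permutation p = 0.00105; median replicate 2 rank 184 against 115, p = 0.0287). All 33 share their list's highest score, so these ranks are the authors' peak numbers, which among tied peaks elsewhere followed the combined q-value with a rho of 0.58 and 0.53. In each group, a pair of overlapping replicate 1 peaks shares a replicate 2 rank (28 with a combined region, 288 without). The replicate 2 test therefore counts these more than once, and it was not repeated without them. A stricter scale on chromosome I would turn its q-values weaker at a given rank, and they lay a mean of 4.73 log10 units above the line fitted elsewhere (bootstrap interval 3.90 to 5.49, with an SD of 10.3 around the line elsewhere); against the 20 regions nearest in rank the median excess was 1.38 log10 units, above 0 for 18 of 19 regions and for 196 of 409 elsewhere (two-sided permutation p = 2.00e-05 for each, the smallest possible). A hypothesis is that the input was scaled per chromosome and that the broad region at the end of chromosome I, or the aha-1 transgene, whose gene is on chromosome I in WBcel235, weighed on that scale, which was not tested and needs reads. Broad regions among the 5 lowest q-values also lay on V, II and III, where 21 of 21, 39 of 40 and 51 of 53 reproduced strong peaks were covered. A broad region with a low q-value alone therefore does not go with the loss. This does not test the hypothesis, because a q-value does not measure coverage. The regions on V, II and III also held replicate peaks, while the one on chromosome I held none.

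The broad regions may reflect raised coverage over a whole segment, as at repeats or extra DNA copies, or binding spread over it. Of the 10 regions of 1500 bp or more, 3 held one of the 474 strongest peaks of both replicates, against 8 of the 10 narrower regions with the lowest q-values (odds ratio 0.123, 95% interval 0.00787 to 1.13, two-sided Fisher's exact p = 0.0698). The direction is the one that raised coverage predicts against point binding, but the test did not pass. The cutoff of 474 falls within the tied highest scores of both lists, so the direction rests in part on peak numbers. Broad regions V from 1432017 (ranks 494 and 24), III from 10904028 (1004 and 30) and IV from 14032571 (528 and 90) held highest-score peaks of both lists but were not counted. The uncounted narrower regions, V from 264905 (1802 and 165) and III from 10224464 (416 and 1294), did not. Binding spread over a segment would give the same direction, so this test cannot tell the 2 explanations apart. The pair on chromosome III from 10904028 to 10909768 is on the chromosome of unc-119 in WBcel235, the marker carried by the transgene, and whether it lies at that gene was not analysed here.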
